A study of Camponotus floridanus with 15 samples.

How the data were processed

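Whole-body RNA was extracted with TRIzol and treated with DNase, and poly(A) RNA was made into strand-specific libraries with dUTP in the second strand, per the labels' protocols. STAR 2.5.0b and DESeq2 are named in the submitters' processing notes, which give no role for either. The genome build, the annotation and the way reads were counted are not given in the sources used here. The deposited table holds RPKM (reads scaled by gene length and by a total per library), per the labels and its own values, for 18979 genes in 15 libraries. Its columns were matched to samples by their 2 header lines, of which the first names the minor samples minor and the second worker, and 0 columns were left without a sample. The sources give no batch. All column names open with the same prefix, and the sources used here do not say what it stands for.

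The IDs are of 2 kinds, 18620 with the prefix CFLOG and 359 with the prefix XLOC. None of them (0) matched the 14020 genes of the RefSeq table of this species, and the deposited table holds no names. The 34 gene lists fixed before the data were examined therefore could not be matched to IDs, and the planned list tests were not run. Named genes follow a rule written before the data were examined: where IDs have no names, at most 2 IDs that rose and 2 that fell per comparison, those of the largest change past the threshold. Near-identical copies and overlapping models cannot be looked up here, so reads that the counting divided between copies would leave single values uncertain.

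Depth was recovered from the values. RPKM of a low gene moves in steps of 1 read, and the steps gave each library's divisor (16740000 to 34150000 reads) and the length of 14301 genes. Among values under 1000 reads on those genes, 100% came out whole within 0.05 in every library. This follows from how the lengths were chosen and is no separate check. Reads on genes with a length were 23.2% to 44.5% of the divisor, and what the remainder of the divisor counts is not given in the sources used here. Lengths of CFLOG genes were multiples of 3 in 90.1% (first number series) and 96.7% (second number series) of cases, so they are mostly coding lengths without UTRs. XLOC lengths were multiples of 3 in 30.7%. On simulated tables of 18979 genes a length was recovered for 72.8%, and 99.6% of those were right. Recovered reads were used for depth and floors, and no count test was run. A value of 0 was given a floor of 3 reads per library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared only to find repeated deposits of one library, and none was found: the chi-square per gene with 1 degree of freedom, over genes with at least 20 reads in the pair, had a median between 2.43 (early pupa) and 9.12 (minor) and a mean between 41.7 (embryo) and 159.6 (minor).

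Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with 1 term per group, all 15 libraries in the fit and eBayes with a trend. Genes with at least 1 RPKM in at least 2 libraries were kept (10807). Tests were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The 7 comparisons are the steps from embryo through instar 1 larva, instar 4 larva, early pupa and late pupa minor to minor, then late pupa major against late pupa minor and male against minor. An F test covered all groups. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Means and SDs are of RPKM, and SEs are limma's.

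RPKM of a library depends on what its other transcripts take up, and the median of all genes moved by up to -1.02 between neighbouring stages. All counts are therefore also given after dividing each library by its median ratio to the geometric mean over the 9990 genes above 0 in every library. The factors ran from 0.495 (instar 4 larva replicate 1) to 2.319 (embryo replicate 1). Principal components and correlations use the rescaled values.

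The limma step was tested on simulated data with 200 changed genes. For embryo to instar 1 larva (10180 genes) it recovered 5.9% of changes of 1 log2 unit, 60% of 2 and 88.1% of 3, with 9 false calls. For late pupa minor to minor (10209 genes) the shares were 7.7%, 85.5% and 87.9%, with 13 false calls beside 122 true ones, the most false calls of the 7 comparisons. For late pupa major against late pupa minor (10207 genes) the shares were 9.1%, 54.7% and 77.1%, with 7 false calls. For male against minor (10207 genes) they were 0%, 45.8% and 69.8%, with 5 false calls. The other comparisons had 6 false calls (instar 1 to instar 4 larva), 7 (instar 4 larva to early pupa) and 4 (early pupa to late pupa minor). Each run drew 1 set of genes, gave all libraries of a gene 1 mean and 1 spread apart from the change, and held no shift of scale. The shares therefore do not rank the comparisons other than that of male, and they leave out the larger spread of late pupa minor. A gene without a call may still have changed by 1 log2 unit or more.

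Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter on low values, a filter of 5 RPKM, median-ratio rescaling, the replicate number as a block, a fit on only the groups compared, and leaving out each replicate in turn. Rescaling combined with a left-out library was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.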

Results

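Poly(A) RNA from whole bodies of the carpenter ant *Camponotus floridanus* was sequenced at successive stages of development, in libraries that keep the strand of the transcript. The 15 libraries fall into 8 groups: embryo, instar 1 larva, instar 4 larva, early pupa, late pupa of the minor caste, late pupa of the major caste, minor and male. Minors and majors are the small and the large workers of this species. The 7 groups other than male have 2 libraries each, and male has 1. The work was done for a long-read reassembly of ant genomes, so the libraries also served to describe gene models over development. Nothing in the labels says whether the replicates came from separate colonies or animals, so p-values measure only the spread between these samples, which may be technical. The table lists RPKM for 18979 genes. The read numbers behind it, recovered from the steps of the values, ranged from 4020000 in late pupa minor replicate 2 to 11240000 in minor replicate 1. On a gene of 1000 nt, 3 reads correspond to between 0.088 RPKM in minor replicate 1 and 0.179 RPKM in embryo replicate 1. The files pair no ID with a gene name, so genes are given by ID and no function is stated.

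Most expressed genes varied among the groups. Across all 8 groups, which differ in caste and sex as well as stage, 9594 of 10807 tested genes (88.8%) varied at an adjusted p under 0.05 in limma's F test, and 7658 of 10630 (72%) varied after the libraries were rescaled by median ratios. The first 2 principal components carried 33.2% and 28.3% of the variance after rescaling. Embryo, larvae and early pupa lay at one end of the first component (24.3 to 65.3, with early pupa at 32.3 and 38.5) and minor at the other (-97.2 and -82.5). Late pupae lay highest on the second component, between 46 and 76.5, followed by early pupa at 32.1 and 34.1. Late pupa minor replicate 2 correlated more with late pupa major replicate 1 (0.94) than with its own replicate (0.924). Across genes, which are not independent replicates, the mean correlation between groups was highest for embryo with instar 1 larva (Pearson r = 0.925), followed by the late pupae of the 2 castes (0.911), instar 1 with instar 4 larva (0.897) and minor with male (0.891). Replicates correlated at 0.924 in late pupa minor and at 0.958 to 0.974 in the other groups of 2.

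**Figure D1:**
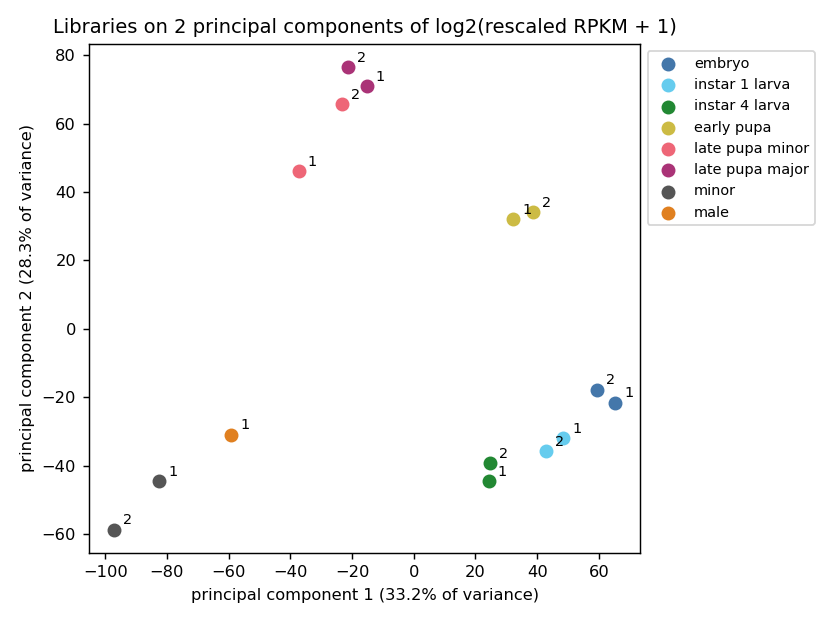
Each point is a library, placed by its scores on principal component 1 (x axis, 33.2% of variance) and 2 (y axis, 28.3%) of log2(median-ratio rescaled RPKM + 1), coloured by group and numbered by replicate. Embryo and larvae sit at the lower right, early pupa above them (32.1 and 34.1 on the second component), late pupae at the top and minor and male at the lower left, and the late pupa minor libraries lie apart from each other (46 and 65.6 on the second component).

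A few transcripts took much of the RPKM total in larvae and pupae. CFLOG000597.1 was the most abundant gene in embryo and both larval stages, at 2.1% and 2.87% of the RPKM total in embryo and 13.95% and 9.16% in instar 4 larva. It gave way in early pupa to CFLOG010137.2 and CFLOG007438.2, which took 13.15% and 11.02% of the total in replicate 1 and 12.44% and 9.74% in replicate 2. In late pupae CFLOG025650.1 took 17.9% and 16.28% of the total in minor and 11.28% and 13.46% in major. CFLOG005200.2, named here because it led a library and so chosen after its values were seen, took 14.67% and 10.23% in late pupa major and 4.77% and 5.76% in late pupa minor. By their most abundant gene the minor and male libraries were more even than larvae and pupae: it took 2.75% and 2.2% in minor and 1.41% in male. The 50 most abundant genes took 32.31% and 35.76% in minor, near the 32.59% and 37.34% of instar 1 larva. Of genes that peaked in one group by at least 2 log2 units over every other group, 25 peaked in early pupa and made up 37.56% and 41.88% of the RPKM total in that group's libraries, against at most 3.08% in any other library. After rescaling 27 genes met that rule in early pupa, 22 of them in both lists. Genes expressed only in the 1 male library were not tested and could not meet the rule. Late pupal genes alike in both castes, such as CFLOG025650.1 (mean of 49850 RPKM in minor and 39080 in major), could not meet the rule in either caste. Genes that met it under both scalings numbered 40 for minor, 36 for male, 24 for instar 4 larva, 19 for late pupa major, 13 for embryo, 2 for instar 1 larva and 0 for late pupa minor.

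**Figure D2:**
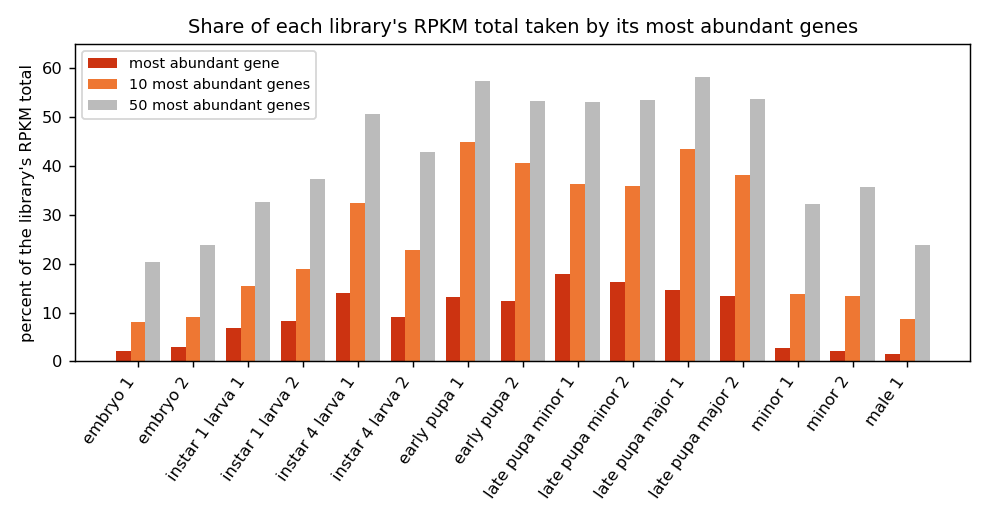
Bars give the percent of each library's RPKM total (y axis, from 0) taken by its most abundant gene and by its 10 and 50 most abundant genes, for the 15 libraries in order of development (x axis). The 10 most abundant genes take 8.1% and 9.07% of the total in embryo, 44.84% and 40.71% in early pupa and 8.77% in male.

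**Figure D3:**
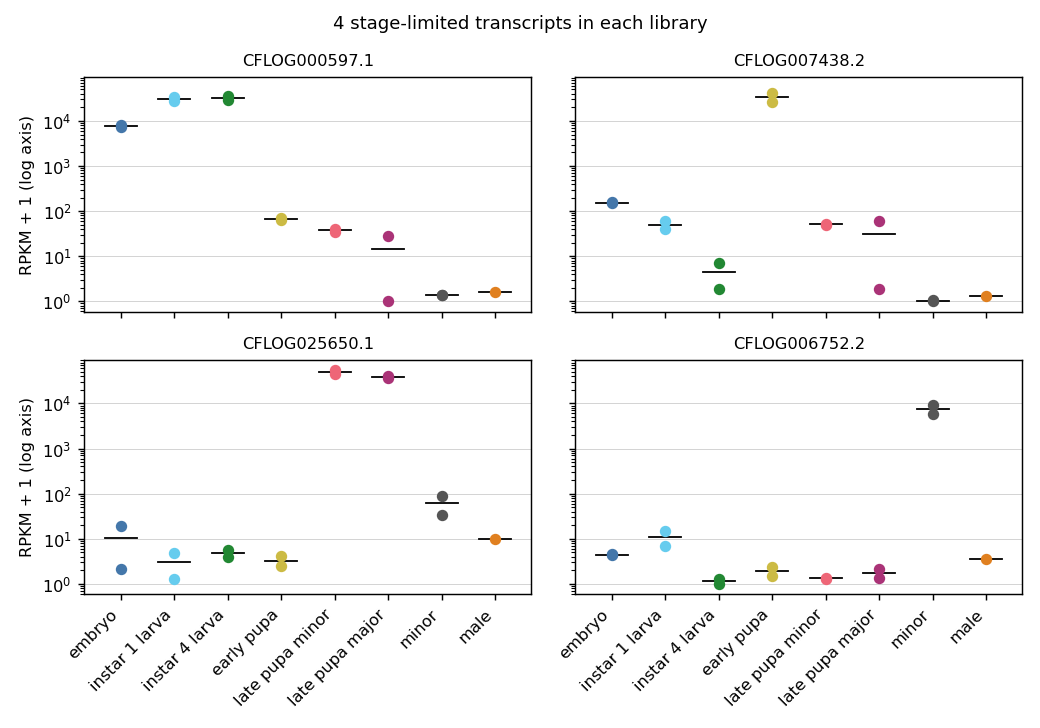
RPKM + 1 on a log axis (y) of 4 transcripts in every library (points), by group (x axis), with the group mean as a line. CFLOG000597.1 is highest in larvae, CFLOG007438.2 in early pupa, CFLOG025650.1 in late pupae of both castes and CFLOG006752.2 in minor.

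From embryo to instar 1 larva, the change at hatching, 154 genes rose and 165 fell of 10807 tested (limma, adjusted p under 0.05). The median of all genes moved by -0.08 on the log2 scale. CFLOG009872.1 rose from 46.3 ± 55.7 to 522.9 ± 315.1 RPKM (SD, n = 2 each), a log2 change of 4.18 ± 0.73 (SE, adjusted p = 0.0023), and was at 810.1 ± 360.1 in instar 4 larva before it stood at 1.32 ± 0.131 in early pupa. CFLOG007104.2 rose from 1.19 ± 0.195 to 28.3 ± 6.53 RPKM (log2 change 3.73 ± 0.85, adjusted p = 0.018). On the log2(RPKM + 1) scale the largest decrease was that of CFLOG008802.1, from 243.7 ± 81.5 RPKM in embryo to 8.54 ± 11.2 in instar 1 larva (log2 change -5.49 ± 0.77, adjusted p = 0.00068). CFLOG004601.2 fell from 167.1 ± 52.6 to 8.1 ± 8.33 RPKM (log2 change -4.56 ± 0.67, adjusted p = 0.00069) and was later at 563.3 and 615.6 RPKM in the early pupa libraries. With rescaled libraries 132 genes rose and 94 fell, 87 and 78 of them in the same direction as on the deposited scale, and CFLOG007104.2 no longer passed (adjusted p = 0.14). Leaving out 1 library also ended calls. CFLOG009872.1 changed by 5.9 without embryo replicate 1, by 2.45 without embryo replicate 2 and by 3.52 without instar 1 larva replicate 2 (adjusted p = 0.058 in each of the last 2), and it also missed the threshold with a pseudocount of 0.1 (0.053) or no filter (0.068). CFLOG007104.2 missed it without embryo replicate 1 (0.33), embryo replicate 2 (0.13) or instar 1 larva replicate 2 (0.19) and with no filter (0.18), and CFLOG004601.2 without embryo replicate 1 (0.068). Without instar 1 larva replicate 1 and 2 the change of CFLOG008802.1 was -7.21 and -3.77 and that of CFLOG004601.2 -5.68 and -3.45. The direction with more genes changed with the library left out: 39 rose and 9 fell without embryo replicate 1, 57 rose and 264 fell without embryo replicate 2, 163 rose and 331 fell without instar 1 larva replicate 1, and 28 rose and 22 fell without instar 1 larva replicate 2.

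Between instar 1 and instar 4 larva the direction of most calls depended on the scale. On the deposited scale 149 genes rose and 5375 fell, with a median log2 change of -1.02 over all genes. After rescaling 548 rose and 286 fell. The median change was then 0, which follows from how the libraries were rescaled and is no separate result. Calls made in one direction under both scalings numbered 144 genes that rose and 286 that fell. Among these, CFLOG003834.2 rose from 0.232 ± 0.0918 RPKM in instar 1 to 257.8 ± 23.3 in instar 4 (log2 change 7.71 ± 0.31, adjusted p = 5.1e-13; 8.73 above the median of all genes). It stood under 1 RPKM in each of the other groups' libraries. CFLOG002453.2 rose from 0.735 ± 0.235 to 369.3 ± 245.6 RPKM (log2 change 7.57 ± 0.55, adjusted p = 1.1e-08). In the other direction, CFLOG007208.2 fell from 1008 ± 312.4 to 4.17 ± 4.37 RPKM (log2 change -7.89 ± 0.76, adjusted p = 5.8e-07; -6.87 against the median), and CFLOG002847.2 from 313.8 ± 111.4 to 0.498 ± 0.24 RPKM (log2 change -7.68 ± 0.72, adjusted p = 4.1e-07). On the deposited scale the count of 5524 was 2313 and 2543 without either instar 1 library and 2101 without instar 4 larva replicate 1, whose RPKM total (204206) was below that of replicate 2 (390039). The rescaled count of 834 was 1015 without instar 4 larva replicate 1.

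Pupation brought the largest single changes up to that point on the log2(RPKM + 1) scale. From instar 4 larva to early pupa 749 genes rose and 468 fell, with a median log2 change of 0.3, but which direction held more genes depended on single libraries: without instar 4 larva replicate 1, 223 rose and 599 fell, and without replicate 2, 1393 rose and 311 fell. Rescaled, 941 rose and 1089 fell (366 and 745 without instar 4 larva replicate 1), and 710 rising and 465 falling genes were called under both scalings. CFLOG007438.2 went from 3.51 ± 3.74 to 34340 ± 10580 RPKM (log2 change 13.16 ± 0.93, adjusted p = 1.9e-09) and CFLOG010137.2 from 4.94 ± 4.95 to 42090 ± 11030 RPKM (13.07 ± 0.8, adjusted p = 2.2e-10). The 2 genes named for the largest decreases were CFLOG000597.1 and CFLOG020325.1. CFLOG000597.1 dropped from 32110 ± 5135 to 66.05 ± 6.1 RPKM (log2 change -8.9 ± 0.85, adjusted p = 1.7e-07). It was later at 27.4 RPKM in late pupa major replicate 1 and 0 in replicate 2. CFLOG020325.1 dropped from 1865 ± 207.8 to 2.93 ± 0.998 RPKM (log2 change -8.91 ± 0.5, adjusted p = 1.1e-10). The early pupa levels of both genes may hold reads carried over from larval libraries, which was not tested there, so the sizes of these falls are uncertain. The 17 larval transcripts examined under the other observations had a median of 0.0904% and 0.135% of their instar 4 reads in the early pupa libraries. The count of 1217 fell to 540 without early pupa replicate 1 (217 rose and 323 fell), to 691 without early pupa replicate 2 and to 738 with no filter on low values.

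**Figure D4:**
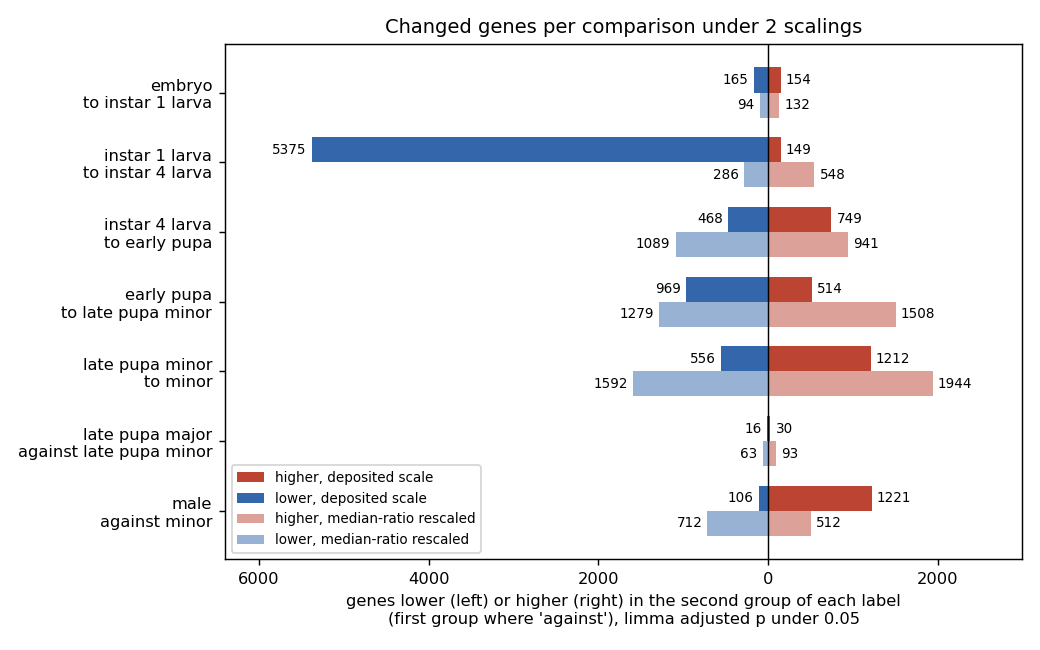
Bars give the number of genes called lower (left) and higher (right) at an adjusted p under 0.05 in limma (x axis), for each comparison (y axis), on the deposited RPKM scale (dark) and after median-ratio rescaling (light). For instar 1 to instar 4 larva 5375 genes are lower on the deposited scale and 286 after rescaling, and for male against minor the majority turns from 1221 higher to 712 lower.

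From early pupa to late pupa minor 514 genes rose and 969 fell (median log2 change -0.28), and rescaled 1508 rose and 1279 fell. Under both scalings 512 genes rose and 917 fell. CFLOG025650.1 rose from 2.27 ± 1.2 to 49850 ± 6418 RPKM (log2 change 13.94 ± 0.75, adjusted p = 4.2e-11), the largest change in any of the 7 comparisons on the log2(RPKM + 1) scale. CFLOG001115.2 rose from 3.41 ± 1.92 to 6081 ± 2669 RPKM (10.43 ± 0.55, adjusted p = 3.1e-11). The early pupal pair fell back: CFLOG007438.2 to 49.7 ± 1.66 RPKM (log2 change -9.37 ± 0.93, adjusted p = 4.6e-07) and CFLOG010137.2 to 72.4 ± 1.49 RPKM (-9.14 ± 0.8, adjusted p = 6.1e-08). Late pupa major replicate 1 had levels like those of late pupa minor and replicate 2 did not: CFLOG007438.2 was at 59.2 and 0.892 RPKM and CFLOG010137.2 at 76.6 and 4.84. The late pupa minor libraries differed more than other replicates, with 166 genes at least 4 times apart after rescaling against 27 to 56 in the other pairs. The majority turned without late pupa minor replicate 2 (531 rose and 436 fell) and without early pupa replicate 1 (324 rose and 300 fell). The count of 1483 was 765 without early pupa replicate 2 and 887 with no filter, and the rescaled count of 2787 was 2337 without late pupa minor replicate 1.

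The step from late pupa minor to minor called more genes than any other stage step after rescaling. On the deposited scale 1212 genes rose and 556 fell (median log2 change 0.09), and rescaled 1944 rose and 1592 fell. Those called under both scalings were 1207 that rose and 552 that fell. CFLOG006752.2 rose from 0.307 ± 0.0929 to 7580 ± 2636 RPKM (log2 change 12.46 ± 0.45, adjusted p = 8.8e-14). CFLOG002738.2 rose from 0.234 ± 0.0784 to 3474 ± 4155 RPKM (10.56 ± 0.66, adjusted p = 1.4e-10), with 536.2 RPKM in minor replicate 1 and 6413 in replicate 2, and a log2 change of 12.34 without replicate 1 and 8.77 without replicate 2. Among late pupal transcripts, CFLOG001115.2 fell from 6081 ± 2669 to 2.23 ± 0.959 RPKM (-10.84 ± 0.55, adjusted p = 8e-12) and CFLOG027552.1 from 7636 ± 3506 to 4.03 ± 2.03 RPKM (-10.55 ± 0.48, adjusted p = 1.9e-12). In the late pupae of the major caste CFLOG001115.2 stood at 11377 and 8426 RPKM and CFLOG027552.1 at 16386 and 11793. The majority turned without minor replicate 1, where 657 genes rose and 680 fell, and without minor replicate 2 1035 rose and 267 fell. The count of 1768 was 991 without late pupa minor replicate 2 (551 rose and 440 fell), and the rescaled count of 3536 was 3012 without late pupa minor replicate 1.

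Between late pupae of the major and of the minor caste 46 of 10807 genes passed the test, 30 higher in major and 16 lower, against 93 and 63 after rescaling, and 23 and 16 were called under both scalings. The number of genes that differ is not known from these counts. The test recovered 9.1% of simulated changes of 1 log2 unit and 54.7% of 2, in a simulation without the larger spread of the late pupa minor libraries. An unadjusted p under 0.05 was found for 994 of 10807 genes (2433 of 10630 after rescaling). If no gene differed, a share of 0.05 of the genes tested would be expected there. The median log2 difference was 0.06. CFLOG012455.2 was lower in major, at 21 ± 6.98 RPKM against 4002 ± 5008 in minor (log2 difference -6.44 ± 0.76, adjusted p = 0.00018), although the minor libraries themselves lay at 7543 and 460.4 RPKM and the difference was -4.43 without late pupa minor replicate 1 and -8.46 without replicate 2. CFLOG010139.2 showed the same spread, with 2396 and 55.8 RPKM in minor against 4.3 ± 0.177 in major (-6.12 ± 0.95, adjusted p = 0.0035), and differed by -3.42 without late pupa minor replicate 1 and by -8.82 without replicate 2. In early pupa CFLOG012455.2 and CFLOG010139.2 stood at 817.2 and 563.9 RPKM. From there they changed by 1.19 and -0.59 to late pupa minor (limma, adjusted p = 0.32 and 0.73) and by -5.25 and -6.71 to late pupa major. The labels give no age of the pupae, so a difference in age cannot be told apart from caste. CFLOG007208.2, which also fell between instar 1 and instar 4, was higher in major at 342.4 ± 105.5 RPKM against 30.8 ± 34.6 (4.05 ± 0.76, adjusted p = 0.014). CFLOG000471.2 was at 161.5 ± 205.1 RPKM in major and 3.63 ± 0.82 in minor (4 ± 0.71, adjusted p = 0.011), and it was at 0.311 RPKM or less in every library other than late pupa. Its major libraries lay at 306.6 and 16.5 RPKM, and the log2 difference was 1.93 without late pupa major replicate 1 and 6.06 without replicate 2. Both genes higher in major lost their call after rescaling (adjusted p = 0.055 and 0.053), with a pseudocount of 0.1 (0.059 and 0.12) and with no filter (0.26 and 0.27), where CFLOG010139.2 lost it too (0.15) and 9 genes were higher and 13 lower. CFLOG007208.2 differed by 2.58 without late pupa minor replicate 1 (adjusted p = 0.22), by 5.52 without late pupa minor replicate 2 and by 3.73 without late pupa major replicate 1 (0.072). The count of 46 was 21 without late pupa minor replicate 1, 211 without late pupa minor replicate 2 and 16 without late pupa major replicate 2, and limma on these 4 libraries alone called 0 genes, with 1405 at an unadjusted p under 0.05.

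The male library was set against the minor libraries, males against workers. The male group has no replicate check: its 1 library was taken to vary like the other groups, so SEs and p-values hold no spread between males. The filter of 1 RPKM in at least 2 libraries also left out genes expressed only in male, so the genes higher in male exclude these. On the deposited scale 1221 genes were higher in male and 106 lower, with a median log2 difference of 0.61. Rescaled, the majority turned: 512 were higher and 712 lower, and the genes called in one direction under both scalings numbered 504 higher and 104 lower. CFLOG026601.1 stood at 264.3 RPKM in male and 0.597 ± 0.159 in minor (log2 difference 7.38 ± 0.42, adjusted p = 3.2e-10; 6.77 above the median of all genes), and at 2.96 RPKM or less in every other library. CFLOG004940.1 was at 329.6 RPKM in male and 2.09 ± 0.0458 in minor (6.74 ± 0.61, adjusted p = 3.7e-07). CFLOG006752.2, the most abundant gene of minor replicate 1, was at 2.53 RPKM in male (-11.02 ± 0.56, adjusted p = 5.9e-11). CFLOG023792.1 had 0 reads in male and 834.6 ± 138.2 RPKM in minor (adjusted p = 4.1e-06). With 3 reads as the floor for male (0.505 RPKM), it was at least 1650-fold lower there. The count of 1327 was 3150 without minor replicate 1 and 152 without minor replicate 2.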

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

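The scaling of the libraries moved more counts past 1.5 times than the filter or the pseudocount did. Median-ratio rescaling changed the count of called genes from 5524 to 834 (instar 1 to instar 4 larva), 1217 to 2030 (instar 4 larva to early pupa), 1483 to 2787 (early pupa to late pupa minor), 1768 to 3536 (late pupa minor to minor) and 46 to 156 (late pupa castes). The cause was not tested beyond the tests on instar 4 larva given with the other observations. Rescaling without a library that stands apart was added after the data were seen. It gave 1015 and 1111 for the comparisons of instar 4 larva with instar 1 larva and early pupa (without instar 4 larva replicate 1), and 2337, 3012 and 83 for those of late pupa minor with early pupa, minor and late pupa major (without late pupa minor replicate 1). A pseudocount of 0.1 gave 86 for embryo to instar 1 larva, 12 for the castes and 698 for male against minor. No filter on low values, with 16030 genes tested, gave 738 for instar 4 larva to early pupa, 887 for early pupa to late pupa minor and 22 for the castes. Limma on only the groups compared, with fewer residual degrees of freedom, gave 892 for embryo to instar 1 larva, 2319 for early pupa to late pupa minor, 1000 for late pupa minor to minor, 218 for male against minor and 0 for the castes (1405 at an unadjusted p under 0.05). A filter of 5 RPKM left all 8 counts within 1.5 times.

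Leaving out each replicate of the compared groups in turn, with a lone sample taken to vary like the other groups, gave these ranges, for which the cause was not tested. Totals hide turns of direction: a left-out library turned the majority of calls in embryo to instar 1 larva, instar 4 larva to early pupa, early pupa to late pupa minor and late pupa minor to minor. The count ran from 48 (without embryo replicate 1) to 494 (without instar 1 larva replicate 1) for embryo to instar 1 larva, from 2101 to 7478 (without instar 4 larva replicates 1 and 2) for instar 1 to instar 4 larva, from 540 (without early pupa replicate 1) to 1704 (without instar 4 larva replicate 2) for instar 4 larva to early pupa, from 624 (without early pupa replicate 1) to 1120 (without late pupa minor replicate 1) for early pupa to late pupa minor, and from 991 (without late pupa minor replicate 2) to 1531 (without late pupa minor replicate 1) for late pupa minor to minor. For the castes it ran from 16 (without late pupa major replicate 2) to 211 (without late pupa minor replicate 2), and for male against minor from 152 (without minor replicate 2) to 3150 (without minor replicate 1). Genes varying among all groups stayed between 7129 and 9822 under every alternative, but the number tested changed. The 7129 were of 7726 genes tested (filter of 5 RPKM) and the 9822 of 10791 (without instar 4 larva replicate 2). With no filter 9589 of 16030 varied. Of 268 values of the named genes' log2 changes, 245 kept direction and call, 23 kept direction and lost the call, and 0 reversed. These genes were named for the largest called changes, so reversals were unlikely from the start and the values do not speak for other calls. Settings in which a gene missed the filter gave no value.

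With the replicate block the male comparison gave 708 genes in place of 1327, and the other 7 counts stayed within 1.5 times. No pairing of the samples by replicate number was seen. Over 21 pairs of groups, deviations of same-numbered libraries correlated between -0.36 and 0.23 after rescaling, with 4 pairs over 0.1. With 2 libraries per group, a shared origin masked by other differences cannot be excluded. The gene lists were not run for lack of names. No comparison has 3 libraries in both groups, so other splits of the samples were not counted. Recovered reads were fewest in late pupa minor replicate 2 (4020000), and how far depth limits the calls was not tested.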

Other observations

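The tests on overlaps, on the ID series, on minor RNA, early pupa RNA and age in late pupa minor and on larval transcripts in late pupae were chosen after the result was seen. Of the 6 overlaps taken, the one with the highest ratio to independent lists was in larval genes. There 94 genes rose from embryo to instar 1 larva and fell from instar 4 larva to early pupa. Independent lists of 154 and 468 genes would share 6.7. The comparisons share no group, but both take a gene's spread from 1 fit on all 15 libraries, so the lists are not independent. Rescaled, the overlap was 101 against 13.5. Of genes that rose from early pupa to late pupa minor, 139 fell between late pupa major and minor (40 for independent lists), and they made up as much as 45.8% of a library's RPKM total. Rescaled, that overlap was 299 against 269.1, so its excess depends on the scale. The 4 other overlaps, with various directions, also exceeded independent lists on the deposited scale (22 against 11.4, 28 against 13.4, 35 against 16.7 and 17 against 7.1) and after rescaling (18 against 8.3, 88 against 65.9, 200 against 100.2 and 143 against 77.7), so a share above that of independent lists does not by itself set the first 2 overlaps apart.

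The ID series differed in expression. Of 10818 genes in the first CFLOG number series 79.8% were kept as expressed, of 7802 in the second 23.7%, and of 359 XLOC genes 91.1%. No comparison moved an ID series past the threshold of the limma camera test with an estimated correlation, on either scale (lowest adjusted p = 0.41). That lowest value was for XLOC genes in late pupa major against late pupa minor after rescaling, with 1 gene higher and 8 lower (1 and 19 adjusted over the list alone). Their median log2 difference was -0.25 against 0.01 for other genes, and camera's adjusted p was 1.6e-06 with a preset correlation. The preset correlation, planned for the gene lists, put other cases past the threshold too. On the deposited scale XLOC genes passed for the castes (adjusted p = 1.2e-07), male against minor (0.0033) and early pupa to late pupa minor (0.029). Second-series CFLOG genes passed there from instar 1 to instar 4 larva (0.0033). Rescaled, XLOC genes also passed from instar 1 to instar 4 larva (9.1e-05). The outcome therefore depends on the correlation assumed. Genes with consecutive CFLOG numbers had related profiles over the libraries, with a median r of 0.16 in 6955 pairs against 0 in random pairs, and 271 pairs (3.9%, against 0.2% of random pairs) had r over 0.9. At an ID distance of 2 the median was 0.07 and at 5 it was 0.01. In pairs whose lengths differ by over 20% the median lay 0.14 above that of random pairs (95% bootstrap interval 0.13 to 0.16) and in the 980 pairs with lengths within 20% it lay 0.26 above, and the levels of the 271 pairs had a median absolute log2 ratio of 0.72. Whether the numbers follow the genome is not given in the sources used here.

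The caste comparison rests on late pupa minor libraries that differ from each other more than other replicates do. After rescaling 63 genes were at least 4 times higher in replicate 1 and 103 in replicate 2. Minor RNA mixed into replicate 1 is argued against by 11 transcripts of at least 500 RPKM in minor and under 5 RPKM in replicate 2. They lay in replicate 1 at a median of 0.06% of their minor level (95% bootstrap interval 0.00111% to 0.858%). The median share that the 63 genes would need is 79%, with genes out of reach counted at a share of 1. Only 34 of the 63 could be raised so far at a share under 1. Early pupa RNA is argued against by 46 of the 63 genes, which lie in replicate 1 above 2 times the higher early pupa library, and sampling of few reads by a median of 353 reads in the higher library. Pupae of different age remain a candidate explanation: over the 166 genes the difference between the replicates ranked with that of minor and late pupa major, which share no library with it (Spearman rho = 0.7), against an absolute rho of at most 0.32 for such genes of 4 other replicate pairs, though over all 10630 kept genes, where the test was first set, rho was 0.05, below that of early pupa (0.18) and the absolute rho of the other 3 pairs (0.07 to 0.09), so the pair stands apart by rho only over the genes chosen for lying apart. The sign of the difference does not set this pair apart from early pupa: it agreed for 142 of the 166 genes and for 45 of 56 in early pupa. It agreed for 16 of 30 in embryo, 21 of 45 in instar 4 larva and 4 of 27 in instar 1 larva. Minor and late pupa major differ in caste as well as stage, so these values cannot tell age from a replicate 2 closer to the major caste. Late pupa minor replicate 2 correlated at 0.94 with late pupa major replicate 1 and at 0.924 with its own replicate. Whether caste was mixed in replicate 2 was not tested. The test on early pupa RNA also replaced a first one on 14 abundant early pupa transcripts, whose median of -0.0732% had an interval (-0.29% to 250%) too wide to decide.

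Larval transcripts lay at trace levels in 3 of the 4 late pupa libraries. The 17 transcripts with at least 10000 reads in instar 4 larva and under 1 RPKM in both minor libraries had, as a percent of their instar 4 reads, a median of 0.0616% and 0.0336% in late pupa minor, 0.0387% in late pupa major replicate 1 and 0.000384% in late pupa major replicate 2. Within each of the first 3 libraries the fraction was alike over the transcripts, with a ratio of upper to lower quartile of at most 1.99, against at least 4.3 in embryo, instar 1 larva and early pupa. That likeness was the pattern set for reads carried over from larval libraries, which stay a hypothesis, since the sources give no batch. Fading expression in the pupae also stays open, since the fractions ranked with those in early pupa at a rho of 0.39 or more, between the bounds set for it. Early pupa is no clean comparison for either explanation, since carry-over into it was not tested. Its lower quartile (0.0675% and 0.12%) lay near its median (0.0904% and 0.135%), and only the upper quartile (0.474% and 0.515%) lay far above. CFLOG000597.1 is an example of the trace levels in late pupae, with 39.1, 33.9 and 27.4 RPKM in the first 3 libraries and 0 reads in late pupa major replicate 2. The early pupal CFLOG007438.2 and CFLOG010137.2 showed the same split (48.5, 50.8 and 59.2 against 0.892 RPKM, and 71.3, 73.4 and 76.6 against 4.84), so carry-over, untested for them, may set the size of their fall into late pupa minor.

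Most genes were lower in instar 4 than in instar 1 larva on the deposited scale (median log2 change -1.02, and -0.65 and -1.38 without instar 4 larva replicate 1 and 2). A smaller total over the listed genes is argued against as the whole cause: dividing by the RPKM total left the median at -0.64. Dividing by the total without the 50 most abundant genes left -0.44 (-0.47 to -0.37 over pairs of libraries), so a few abundant genes may account for part of the shift. A change in total RNA per animal or in what the divisor counts cannot be read from these files.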
